A study of Mus musculus with 8 samples.

How the data were processed

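Nuclei from the low thoracic spinal cord of wild-type C57BL/6 mice were profiled by single-nucleus RNA sequencing in 3 experiments with 8 libraries. Per the labels, experiment 1 has 2 uninjured replicates, each with a fraction of GFP-positive neurons traced from the lumbar cord and a fraction of GFP-negative, untraced nuclei. Experiment 2 has 2 libraries after hemisection and 1 uninjured library. Experiment 3 has 1 library of regenerating traced neurons. Groups were taken from the sample titles, which gave 5 groups.

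The authors deposited one matrix of UMI counts, with no normalization, for 19787 genes and 12447 nuclei, together with other tables that hold the names of nuclei, gene symbols and an annotation. Per the submitters' processing notes, Cell Ranger 4.0.0 and Seurat 3 were used with the builds mm10 and GRCm38. The filters on barcodes and genes, the removal of doublets and the method of annotation are not given in the sources used here. The deposited annotation gives each nucleus its library, 1 of 6 classes and, for neurons, 1 of 28 subtypes, and these names were used as deposited. In subtype names D, M and V were read as dorsal, middle and ventral, and E and I as excitatory and inhibitory. Slc17a6 exceeded Gad1 in every subtype with E and fell short of it in every subtype with I. The 1 other column of the annotation was not used. No further filter on nuclei and no doublet caller was applied. Some 4727 nuclei carry no barcode sequence, among them the 238 regenerating nuclei and 4489 nuclei of the uninjured library of experiment 2. Whether several preparations were merged under the name of either library is not given in the sources used here. No nucleus had the same values as another (0 found). No gene of the matrix is named GFP, EGFP or Cre (0 found), so the tracer itself was not analysed here.

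Counts were summed over the nuclei of a library that the annotation calls neurons, 4076 in all. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by group with its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest) in R 4.3.3. All 8 libraries entered one fit with a coefficient per group, which left 3 residual degrees of freedom. A group with 1 library was assumed to vary like the replicated groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 11601 tested genes. Where a paragraph prints an adjusted p without another tool, it comes from this edgeR quasi-likelihood test. Standard errors were derived from the moderated F statistic.

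Shares of subtypes were tested with the same edgeR quasi-likelihood test on numbers of nuclei, with the total of neurons as offset, for the 28 subtypes with at least 10 nuclei. An exact permutation test of the 4 libraries of experiment 1 could not go below a two-sided p of 0.33. Genes within subtypes and non-neuronal classes were tested where each library of experiment 2 had at least 20 nuclei. A total of 24 gene lists and 12 marker lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the other settings tried. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. The 33 lists with at least 3 measured members gave 99 tests over the traced, hemisection and regenerating contrasts. Of the 29 calls of camera, 0 held with an estimated correlation, where the smallest adjusted p was 0.266, and fry called 0. Separability was the AUC on held-out nuclei (3 folds) of a random forest of 100 trees (scikit-learn 1.9.0) between 20 nuclei of each of a pair of libraries, thinned to 2000 UMIs per nucleus, averaged over 20 draws. It is a description of libraries and carries no p.

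Named genes are Hoxa7 and Zfhx3 in every contrast, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 CPM and no overlap between groups, without unnamed gene models and mitochondrial and ribosomal protein genes. Where fewer were called, the rest were taken by smallest p. Of each list described, the 2 to 4 members with the smallest p are named, and of subtypes all called ones, or else the 5 with the smallest p. Genes named beyond this rule were chosen after their values were seen and are named as such. Some genes and subtypes, and results that need them, are not reported here. Fold changes of a group at 0 counts are bounds against a floor of 3 counts over the group. Groups with 1 to 3 counts have the ratio of counts with a 95% interval from an exact binomial test. Intervals and floors cover counting error only. Coordinates come from GENCODE M21 (GRCm38), in which 19616 of the 19787 symbols were found, 19456 of them protein-coding.

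The titles give the traced and untraced fractions of experiment 1 the same animal number, and the deposited nucleus names carry the same prefix for both, so these numbers pair the samples. Across 7030 genes the difference between replicates correlated between fractions with Pearson's r = 0.204. Both hemisection libraries share one prefix, and nothing in the labels says whether they came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 2.80 for traced, 4.43 for untraced and 3.57 for hemisection libraries.

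On simulated counts the test recovered 23.0% of genes changed 2-fold and 79.7% of genes changed 4-fold in the traced contrast. These were 18.1% and 95.8% in the hemisection contrast, and 0.521% and 25.0% in the regenerating contrast. False calls made up 9.43% of the calls with 4-fold changes in the regenerating contrast, and at most 2.78% in the other settings. Every simulated gene had the same spread between libraries, so genes whose UMIs come mostly from single nuclei were not covered. For shares in the traced contrast, an 8-fold rise was recovered in 96.0% of 50 draws. The random forest gave an AUC of 0.484 with no changed genes and 1.0 with 200 changed genes.

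Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, thinned libraries, only the libraries compared, deeper nuclei, balanced composition, each library left out and the animal number as a block. After the data were seen, the untraced libraries of experiment 1 were added as a second uninjured reference, together with fits without the regenerating library, name families (the first part of a subtype name) and another background for separability. Balanced composition kept only types with at least 5 nuclei in each library compared. For the hemisection contrast these were 8 dorsal subtypes, with 77 nuclei per library. For the traced and regenerating contrasts they were the name families DE and VEP, with 15 nuclei per library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.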

Results

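Single-nucleus RNA sequencing of the low thoracic mouse spinal cord gave UMI counts, that is counts of distinct captured transcript molecules, for 12447 nuclei in 8 libraries. In experiment 1, neurons of 2 uninjured replicates were split into traced neurons, which carried GFP taken up from the lumbar walking centres, and untraced nuclei without GFP. In experiment 2, nuclei were taken after a hemisection with natural repair in 2 libraries and from an uninjured control in 1 library. In experiment 3, traced neurons that had regrown after injury were sequenced in 1 library. The annotation calls 4076 nuclei neurons. Traced replicates 1 and 2 held 80 and 25 neurons with 1451849 and 333459 UMIs, and untraced replicates 1 and 2 held 354 and 123 neurons with 3508523 and 893838 UMIs. Hemisection replicates 1 and 2 held 1000 and 108 neurons with 8141448 and 1046173 UMIs. The uninjured library of experiment 2 held 2148 neurons with 20739862 UMIs, and the regenerating library held 238 neurons with 135012 UMIs. Median depth lay between 5767 and 16489.5 UMIs per neuron in all libraries except the regenerating one, where it was 488. The uninjured library of experiment 2 and the regenerating library have no replicate, so their values carry no SD. Expression is in CPM, the counts of a gene scaled to a common total of UMIs of the neurons of a library. Neurons made up 89.6% of the nuclei of hemisection replicate 1 and 7.15% of those of replicate 2.

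The comparison of traced with untraced neurons asked which neurons of the uninjured thoracic cord project to the lumbar walking centres. Some genes of inhibitory and of dorsal neurons were lower in traced neurons. Meis2, Mecom and Zfhx3, which encode transcription factors, were higher in traced neurons, and so was Ntng1, which encodes netrin G1, a membrane-anchored guide of axons and synapses. Sall3, a transcription factor gene, and Arhgap6, which encodes a regulator of the actin skeleton, were lower. Nmu, which encodes the dorsal horn peptide neuromedin U, and Otof, which encodes the vesicle fusion protein otoferlin, were lower as well. In the edgeR quasi-likelihood test 42 genes were called, 13 higher and 29 lower in traced neurons. With the animal number as a block 159 were called, 65 higher and 94 lower, the 42 among them. Meis2 stood at 354 ± 38.0 CPM (SD, n = 2) in traced and 109 ± 12.8 CPM (SD, n = 2) in untraced neurons, a log2 fold change of 1.61 (adjusted p = 0.00778). Ntng1 rose by 1.22 (adjusted p = 0.00778), from 380 ± 51.4 to 934 ± 99.6 CPM (SD, n = 2 each). Mecom, Cul4b, Cachd1 and Cpq rose by 2.65, 2.08, 1.58 and 1.49, although 1 nucleus gave 47 of the 148 Mecom UMIs, 48 of the 194 Cul4b UMIs and 33 of the 164 Cpq UMIs of traced neurons. An alternative added after the data were seen took equal numbers of the name families DE and VEP, 15 nuclei per library. There 0 genes were called and Mecom and Cpq were at −0.88 and −0.77. With so few nuclei, the lost calls cannot tell a balanced mixture from a lack of counts. Dqx1, which encodes a helicase-like protein, had 86 counts in traced and 2 in untraced neurons (ratio 106, 95% counting interval 28.5 to 890), and 59 of the 86 lay in 1 nucleus of the 4 that had any. Arhgap6 fell by 1.90 in log2 units (adjusted p = 0.000831), from 923 ± 26.4 to 261 ± 28.9 CPM (SD, n = 2 each). Nmu, Sall3, Otof, Serpinb1b, Prkcq, Gsap and Ptgds had log2 fold changes of −3.26, −3.34, −2.28, −2.42, −2.34, −2.24 and −3.71. Leaving out traced replicate 1 left 19 genes called, and of the 16 called genes named here by the rule only Dqx1, Ntng1 and Arhgap6 stayed called. Without traced replicate 2 the calls of Gsap, Otof and Ptgds were lost, and without untraced replicate 1 those of Cpq and Ptgds, beside 37 and 93 genes called.

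Zfhx3, a factor of early-born neurons with long axons, was higher in traced neurons by 1.15 in log2 units (adjusted p = 0.0311), at 557 ± 152 against 245 ± 27.8 CPM (SD, n = 2 each). It lost its call without traced replicate 1. With equal numbers of the name families DE and VEP, 15 nuclei per library, Zfhx3 was at −0.14 and not called. Hoxa7, a homeobox gene of trunk segments, was at 48.4 ± 0.651 CPM in traced and 66.1 ± 3.28 CPM in untraced neurons and was not called (adjusted p = 0.641). On chromosome 8 (GRCm38) Zfhx3 lies at 107942644 to 108961630, and Hoxa7 lies on chromosome 6 at 52214491 to 52221854, both protein-coding. Among long-range projection factors all 7 measured members were positive, with 1 called (Zfhx3), 3 adjusted over the list alone and a median log2 fold change of 0.79 (adjusted p = 0.266 with an estimated correlation). Of 4 measured ventral excitatory interneuron factors 0 were called and 2 when adjusted over the list alone, with a median of 3.78 (adjusted p = 0.266 with an estimated correlation). Sim1, which marks V3 excitatory interneurons, had 35 counts against 0, at least 28.8-fold more over the group, and was not called (adjusted p = 0.09). Of 10 inhibitory identity genes 2 were called, both lower, among them Gad1 at −1.62, which encodes an enzyme of GABA synthesis. Another 6 passed when adjusted over the list alone (8 in all, median −1.19, adjusted p = 0.266 with an estimated correlation).

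Some genes of dorsal neurons were lower in traced neurons. Ebf1 and Ebf2, factors of dorsal excitatory neurons, fell by 1.45 and 1.78, as 2 of the 7 measured glutamatergic identity genes (4 adjusted over the list alone, median −0.78, adjusted p = 0.266 with an estimated correlation). Nmu and the peptide gene Npy, at −3.26 and −2.37, were the 2 called of 21 dorsal horn genes (7 lower and 1 higher adjusted over the list alone, median −0.77, adjusted p = 0.266 with an estimated correlation). Of 13 mitochondrially encoded transcripts 11 were positive and 3 were called higher, with mt-Nd3, mt-Atp6 and mt-Co3 at 2.22, 1.22 and 1.11 (7 adjusted over the list alone, median 0.83, adjusted p = 0.266 with an estimated correlation). Of 10 oligodendrocyte markers 1 was called lower, the myelin gene Mal with 2 counts in traced and 89 in untraced neurons (18.0 times lower, 95% counting interval 4.85 to 151). Another 4 passed when adjusted over the list alone (5 in all, median −2.27, adjusted p = 0.266 with an estimated correlation). RNA of glia in untraced neurons was not tested for this list. Neurons made up 84.2% and 92.6% of the nuclei of traced replicates 1 and 2. In untraced replicates 1 and 2 they made up 18.3% and 13.9%. Mecom was the 1 called of 4 endothelial markers (adjusted p = 0.467 with an estimated correlation), and Gad1 the 1 called of 8 neuron markers (adjusted p = 0.266 with an estimated correlation, median −0.41). Of 7 microglial markers and 13 antigen presentation genes 0 were called, with 2 and 0 adjusted over the list alone and medians of 0.86 (mean −0.02) and −0.84. Neither list was called with an estimated correlation, where the adjusted p of antigen presentation genes was 0.729.

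In the edgeR quasi-likelihood test on shares of subtypes 1 of 28 was called. Without traced replicate 1, untraced replicate 1 or untraced replicate 2, 0 were called (3, 5 and 4 subtypes at unadjusted p < 0.05), and without traced replicate 2, 1. DE_Sox5_Qrfpr, an excitatory dorsal subtype, made up 0.625% of traced and 10.1% of untraced neurons and was not called (adjusted p = 0.0632), but with the animal number as a block it was (adjusted p = 0.00669). By name family, a grouping added after the data were seen, the dorsal inhibitory family DI was lower in traced neurons (log2 fold change −2.51, adjusted p = 0.00172). No subtype had 20 nuclei in each of the 4 libraries, so the gene differences could not be tested within subtypes (0 eligible).

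**Figure D1:**
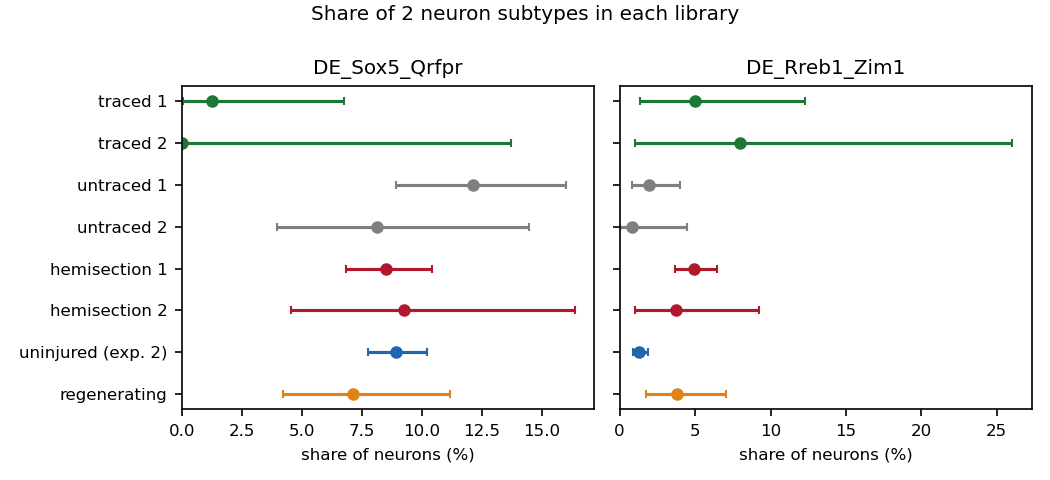
Share of neurons in 2 subtypes (x axis, %) for each of the 8 libraries (y axis), with 95% Clopper-Pearson intervals. The DE_Sox5_Qrfpr share averaged 0.625% in the traced (1 nucleus in all) and 10.1% in the untraced libraries.

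The comparison of hemisected with uninjured cords asked how spinal neurons responded to the injury and its natural repair. Some genes of the interferon response and of antigen presentation were higher in neurons after hemisection, and most genes of cholesterol synthesis were lower. Ifit1 and Oasl2, interferon targets which encode antiviral proteins, rose. H2-K1, which encodes an MHC class I chain, Nlrc5, which encodes its activator, and Herc6, which encodes an interferon-induced ligase, rose too. Chrm4, which encodes the muscarinic acetylcholine receptor M4, had the largest rise of the genes named. In the edgeR quasi-likelihood test 645 genes were called, 110 higher and 535 lower. Ifit1 stood at 83.7 ± 39.7 CPM (SD, n = 2) after hemisection and 3.42 CPM in the uninjured library, a log2 fold change of 4.66 (adjusted p = 0.00037). Oasl2 was at 35.8 ± 11.5 CPM (SD, n = 2) against 1.74 CPM, a log2 fold change of 4.39. Nlrc5, H2-K1 and Herc6 rose by 5.24, 3.68 and 2.89. Chrm4 stood at 93.2 ± 10.2 CPM (SD, n = 2) against 0.145 CPM, with 805 counts against 3 (ratio 606, 95% counting interval 207 to 2943, adjusted p = 5.47e-07). Igkc, the constant part of the antibody kappa chain, had a log2 fold change of 7.40, but a UMI of it lay in 31.7% of neurons and 59.6% of non-neuronal nuclei, so that its share in neurons did not exceed the background. Zfhx3 and Hoxa7 were not called (log2 fold changes 0.16 and 0.08). Without hemisection replicate 1, 171 genes were called, and without replicate 2, 327 genes. All 12 called genes named here by the rule kept their calls in each case.

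Part of the interferon genes rose. Of 11 measured interferon response genes 6 were called, among them Oasl2, Ifit1 and the interferon-induced protease gene Usp18 at 5.74, and 10 passed when adjusted over the list alone (median 2.65, adjusted p = 0.266 with an estimated correlation). Of 13 antigen presentation and complement genes H2-K1 and the MHC class II genes Cd74 and H2-Aa were called (3.68, 4.41 and 4.52), and 8 when adjusted over the list alone (median 2.35, adjusted p = 0.504 with an estimated correlation). The microglial marker Lyz2 was called higher in the same neurons (3.68, adjusted p = 0.0241), and Cd74 stood at 10.4 and 43.0 CPM in replicates 1 and 2. RNA of microglia in these neurons was not tested for this list. Of 15 cholesterol synthesis genes 11 were called lower and 14 when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). Sqle and Msmo1, which encode enzymes of sterol synthesis, had log2 fold changes of −2.63 and −2.25. Of 9 immediate early genes Fos and Egr1, which neurons induce on activity, were called higher (3.67 and 1.68, 2 adjusted over the list alone, median 1.18, adjusted p = 0.289 with an estimated correlation). Among 25 measured regeneration-associated genes the transcription factor gene Sox11 rose by 1.60 and 5 were lower, among them the peptide genes Gal and Npy at −2.25 and −1.90 and Flrt3 at −1.48, a guidance gene. That list was not called by camera (adjusted p = 0.732).

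Many transcripts of energy supply, protein folding and myelin were lower after hemisection than in the uninjured library. All 13 mitochondrially encoded transcripts were called lower (13 adjusted over the list alone, median −2.86, adjusted p = 0.266 with an estimated correlation), among them mt-Atp6, mt-Nd2 and mt-Co2 at −3.53, −3.60 and −2.86. Of 14 heat shock and unfolded protein response genes 9 were called lower (9 adjusted over the list alone, median −1.24), among them the chaperone genes Calr, Hspa5 and Hsp90b1 at −2.25, −1.99 and −1.88. Of 30 ribosomal protein genes 7 were called (19 adjusted over the list alone, median −0.87), Rps29 and Rpl26 among them at −1.99 and −1.55. Of 10 oligodendrocyte markers 9 were called (10 adjusted over the list alone, median −3.00), among them the myelin genes Mobp, Mal and Mbp at −3.70, −3.60 and −1.61. The astrocyte genes Gja1 and Aqp4 were among the 3 called of 6 (3 adjusted over the list alone, median −1.65). The adjusted p with an estimated correlation was 0.266 for these lists except ribosomal protein genes at 0.567. Of 28 axon cytoskeleton genes 6 were called lower, among them the neurofilament genes Nefl, Nefm and Nefh at −2.45, −2.42 and −2.46 (6 adjusted over the list alone, median −0.28, adjusted p = 0.266 with an estimated correlation). The dorsal horn peptide genes Tac1, Sst, Cck and Npy, at −2.26, −2.25, −1.88 and −1.90, were among the 7 called of 21 (7 adjusted over the list alone, median −0.23, adjusted p = 0.266 with an estimated correlation). The choline transporter gene Slc5a7 was the 1 called of 6 motor neuron markers (5 adjusted over the list alone, median −2.74, adjusted p = 0.619 with an estimated correlation). Motor neurons made up 1.12% of neurons of the uninjured library and 0 of 1000 and 0 of 108 neurons of the hemisection libraries, which allows shares of up to 0.3% and 2.78%, and that subtype was not called (adjusted p = 0.331). The test by name family, added after the data were seen, called 4 of 11 families. Among them were the dorsal excitatory family DE, which was higher (log2 fold change 0.34, adjusted p = 0.0019), and the ventral inhibitory family VIP, which was lower (adjusted p = 0.00133). Motor neurons were called lower there (adjusted p = 0.0019), though this family is the same single subtype with the same counts. Their unadjusted p in the edgeR quasi-likelihood test was 0.0261 by subtype and 0.000401 by family. That call thus came from the fit and not from a grouping of nuclei. The untraced libraries of experiment 1, also uninjured, had 54.5% and 57.7% DE and 5.08% and 4.07% VIP, with 0.565% and 0 motor neurons, near the hemisection libraries (DE 53.3% and 58.3%), while the uninjured library of experiment 2 stood apart with 42.4% DE and 10.3% VIP. Slc32a1, which encodes the vesicular GABA and glycine transporter, was at 22.1 ± 2.57 CPM (SD, n = 2) against 151 CPM. Ptgds, Clu, Lrtm1 and Loxl2 had log2 fold changes of −2.93, −2.72, −2.94 and −2.65.

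The untraced neurons of experiment 1 served as a second uninjured reference, chosen after the data were seen, and part of the interferon and sterol genes were called against it as well. Against them 22 genes were called, 16 higher and 6 lower. Called against both references in the same direction were 14 higher and 6 lower genes, where independent lists of these sizes would share 0.152 and 0.277, although both comparisons share the hemisection libraries and are not independent. Over all tested genes the log2 fold changes against the references correlated with a Spearman coefficient of 0.415, and in 20 simulated data sets without effects with 0.417. Among the 14 were Chrm4, Igkc, Iigp1, Usp18, Nlrc5, Gm4951, Ifit1, Oasl2, H2-K1, Ddx60, Herc6, Cd274 and Rnf213. Among the 6 were the sterol genes Hmgcs1, Msmo1, Insig1 and Sqle, with log2 fold changes of −1.48, −1.53, −2.40 and −1.79, and the myelin gene Mal at −2.50. These genes were chosen after their values were seen. Against experiment 1, 4 of the 11 interferon genes were called (9 adjusted over the list alone) and 5 of the 15 cholesterol genes (12 adjusted over the list alone), each with an adjusted p = 0.0932 with an estimated correlation. Of the 13 antigen presentation genes 2 were called there (8 adjusted over the list alone, median 2.19). Of the 13 mitochondrial transcripts 0 were called by edgeR against experiment 1 (2 adjusted over the list alone), with a median of −0.44. Of the 10 oligodendrocyte markers 1 was called there (4 adjusted over the list alone, median −1.42). Called there were 0 of the 30 ribosomal protein, 14 heat shock, 28 axon cytoskeleton, 21 dorsal horn, 6 astrocyte, 6 motor neuron, 9 immediate early and 25 regeneration-associated genes, with 1 higher and 1 lower adjusted over the list alone for astrocytes and motor neurons, and medians of 0.22, −0.19, −0.14, −0.15, 0.25, −1.77, 0.24 and 0.11. Rps29, Rpl26 and Aqp4 were at 0.34, 0.10 and 1.61, Calr, Hspa5 and Hsp90b1 at −0.11, −0.51 and −0.50, and Tac1, Sst, Cck and Npy at −0.53, −0.00263, −0.15 and −0.47. Ptgds, Slc5a7, Slc32a1, Clu, Lrtm1 and Loxl2 had −2.24, −2.32, −1.11, −0.71, −0.38 and −0.03 there, and none was called. Fos was at −0.29 and Sox11 at 0.26. The uninjured references themselves differed in 299 genes, 240 of them higher in experiment 2, with 12 of the 13 mitochondrial transcripts among these (adjusted p = 0.0366 with an estimated correlation). Of the 535 genes lower after hemisection 224 were also called higher in the uninjured library of experiment 2 than in experiment 1, and both comparisons share that library.

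**Figure D2:**
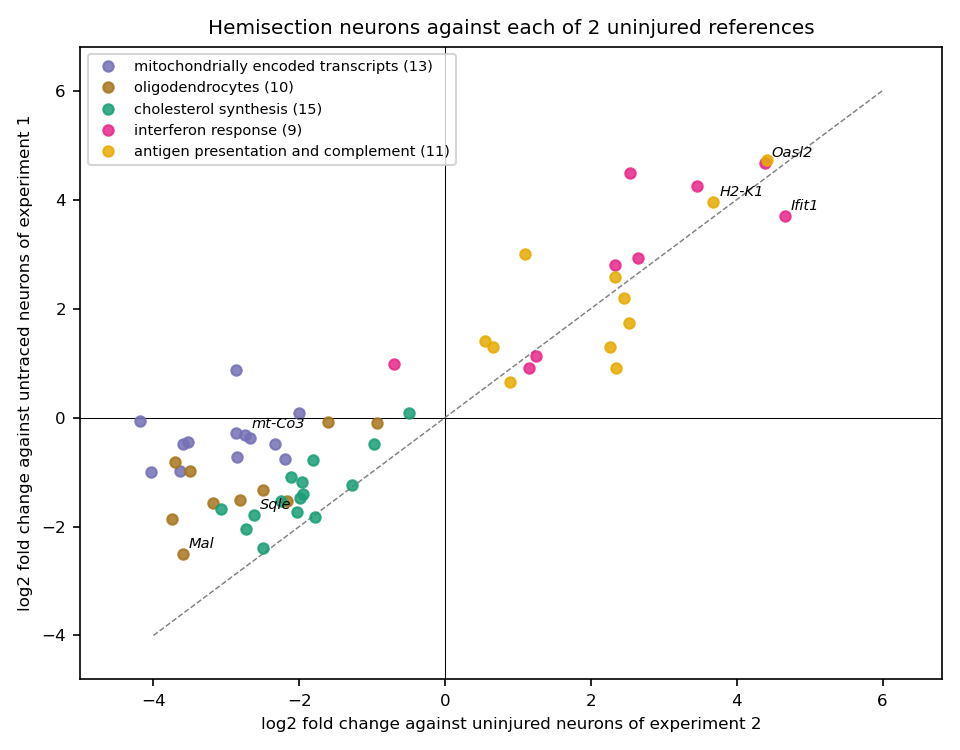
Log2 fold change of 5 gene lists in hemisection neurons against the uninjured library of experiment 2 (x axis) and against untraced neurons of experiment 1 (y axis), for members with counts in each reference. Mitochondrial transcripts had medians of −2.86 on the x axis and −0.44 on the y axis.

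Chrm4, the gene of the muscarinic receptor M4, was seen in part of the neurons after hemisection. It had a UMI in 16.7% of neurons after hemisection (185 of 1108, 95% Clopper-Pearson interval 14.5 to 19.0%, median depth 7269 UMIs) and in 0.132% of non-neuronal nuclei (2 of 1519, median depth 2053 UMIs). At 2000 UMIs per nucleus the shares were 9.07% of 926 neurons and 0.127% of 788 non-neuronal nuclei. At that depth the share differed between subtypes in replicate 1 (permutation p = 1e-05), while replicate 2, with 76 nuclei, gave a permutation p of 0.163. Over both libraries and without equal depth it was 58.3% in MEP_Lmx1b_Satb1 (7 of 12), an excitatory subtype, and 36.0% in MIP_Tfap2b (18 of 50), an inhibitory subtype. In DE_Reln_Nmur2, a dorsal excitatory subtype, it was 3.64% (4 of 110). At 2000 UMIs these shares were 41.7%, 18.4% and 2.20%. Chrm4 lies on the plus strand of chromosome 2 at 91927249 to 91928688 (GRCm38), where no other gene overlaps it.

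**Figure D3:**
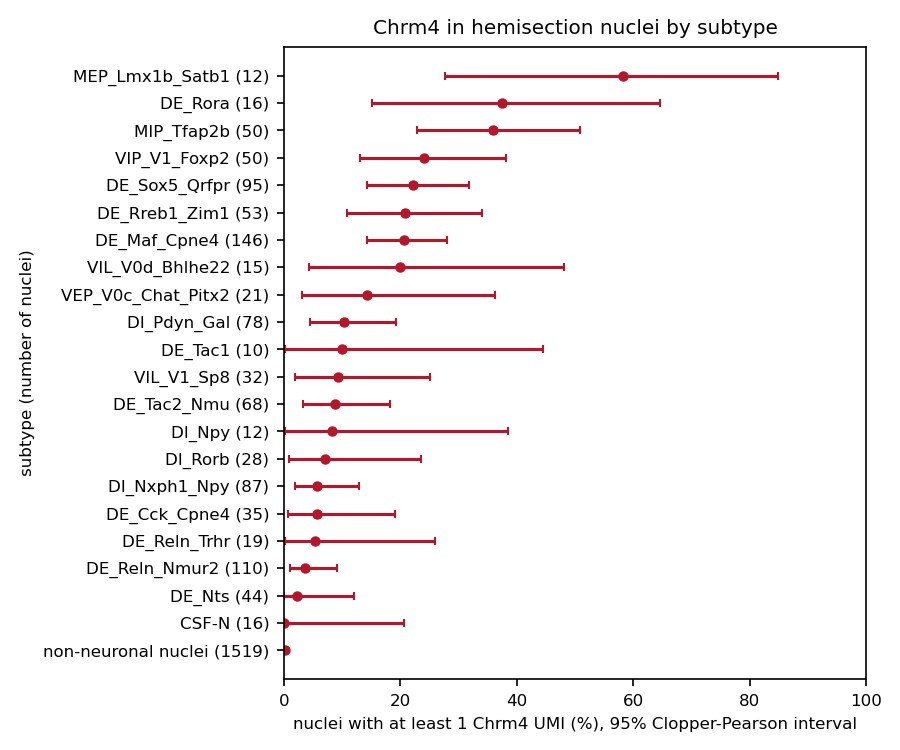
Share of hemisection nuclei with at least 1 Chrm4 UMI (x axis, %) in neuron subtypes and in non-neuronal nuclei (y axis, number of nuclei in brackets), with 95% Clopper-Pearson intervals. The share was 58.3% in MEP_Lmx1b_Satb1 and 0.132% in non-neuronal nuclei.

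Among subtypes, DE_Rreb1_Zim1, a dorsal excitatory subtype, made up 4.30% ± 0.846 (SD, n = 2) of neurons after hemisection and 1.30% in the uninjured library. It was the 1 subtype called in the edgeR quasi-likelihood test (log2 fold change 1.83, adjusted p = 0.0427). No subtype was called without hemisection replicate 1 or replicate 2 (0 and 0 called, 0 and 5 at unadjusted p < 0.05), nor against experiment 1 (0 called, 4 at unadjusted p < 0.05). Within DE_Reln_Nmur2, the 1 subtype with 20 nuclei in each library of experiment 2, 98 genes were called, 10 higher and 88 lower. Cntn4, which encodes the adhesion protein contactin 4, rose there by 1.31, while Nefm and Ptgds were at −4.04 and −3.82. Without hemisection replicate 1 the count was 11 and without replicate 2 it was 47. Cntn4 and Ptgds were the 2 genes of this subtype called against both references, and these 3 genes were chosen after their values were seen. Separability, the AUC with which a random forest told nuclei of a pair of libraries apart, asked which subtypes responded most. In DE_Reln_Nmur2 it was 0.825 and 0.849 between hemisection replicates 1 and 2 and the uninjured library, and 0.573 between the hemisection replicates. Between untraced replicate 1 of experiment 1 and the uninjured library it was 0.897, so that libraries of different experiments were told apart without an injury. By hemisection replicate 1 alone, the ventral inhibitory subtypes VIP_V1_Foxp2 and VIL_V1_Sp8 ranked highest of 14 (0.965 and 0.955), with a median of 0.907 over the 14. In 4 of 7 subtypes the AUC of hemisection replicate 1 exceeded that of experiment 1. Among the 4, DE_Maf_Cpne4 was at 0.8634 beside 0.8631 and DE_Tac2_Nmu at 0.890 beside 0.885. These gaps lay within the SD over draws of hemisection replicate 1 (0.0824 and 0.0592). VIP_V1_Foxp2 and VIL_V1_Sp8 had too few nuclei in experiment 1, so their rank could not be set against that background.

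Nuclei annotated as microglia and oligodendrocytes, the resident immune and the myelin-forming cells, also differed after hemisection. Genes of this paragraph were chosen after their values were seen. Microglia had higher Apoe and Spp1, which encode a lipid carrier and a matrix protein, Lgals3, which encodes a lectin, and the growth factor gene Igf1. Their log2 fold changes were 3.47, 5.27, 6.26 and 4.15. Gpnmb, which encodes a lysosomal membrane protein, was at 1761 ± 259 CPM (SD, n = 2) against 0 counts, at least 544-fold more over the group. The homeostatic microglial genes P2ry12, Tmem119 and Siglech were lower in microglia, at −1.71, −1.81 and −3.43. Oligodendrocytes had higher Oasl2 (7.67), MHC class I genes B2m and H2-D1 (4.31 and 5.04) and complement gene C4b (4.18). The sterol genes Hmgcs1, Msmo1, Sqle and Cyp51 were lower in them, at −2.86, −2.26, −3.05 and −2.89. All these genes were also called against experiment 1. In the edgeR quasi-likelihood test 1525 genes were called in microglia (542 higher, 983 lower) and 1128 in oligodendrocytes (412 higher, 716 lower), with 260 and 144 of the former and 180 and 46 of the latter called against both references. Of 14 interferon genes 12 were higher in microglia and 14 in oligodendrocytes, with 11 and 14 against both references. Of 16 antigen presentation and complement genes these numbers were 13 and 15 (11 and 15 against both references). Of 15 cholesterol genes 12 were lower in oligodendrocytes, 11 of them against both references. Of 10 markers of microglia and macrophages 3 were lower and 1 higher in microglia, with 2 and 1 against both references. Whether an annotated class holds the same kinds of cells in each library was not tested. In oligodendrocytes 2 of 9 markers of microglia and macrophages were higher, 1 of them against both references. Of 3 lymphocyte markers 1 was higher in them, with 0 against both references. RNA of immune cells in nuclei annotated as oligodendrocytes was not tested, also for the antigen presentation and complement genes. Other markers of other cells were lower. Of 8 neuron markers 7 were lower in microglia and 7 in oligodendrocytes, with 0 against both references, and of 10 oligodendrocyte markers 10 were lower in microglia, 2 of them against both references. Snap25, which encodes a synaptic protein, and mt-Co3 were lower in microglia by 5.15 and 2.47, and were not called against experiment 1. Hemisection replicates 1 and 2 held 32 and 593 microglia and 62 and 765 oligodendrocytes. Over these classes 2653 genes were called, 2668 without replicate 1 and 442 without replicate 2.

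**Figure D4:**
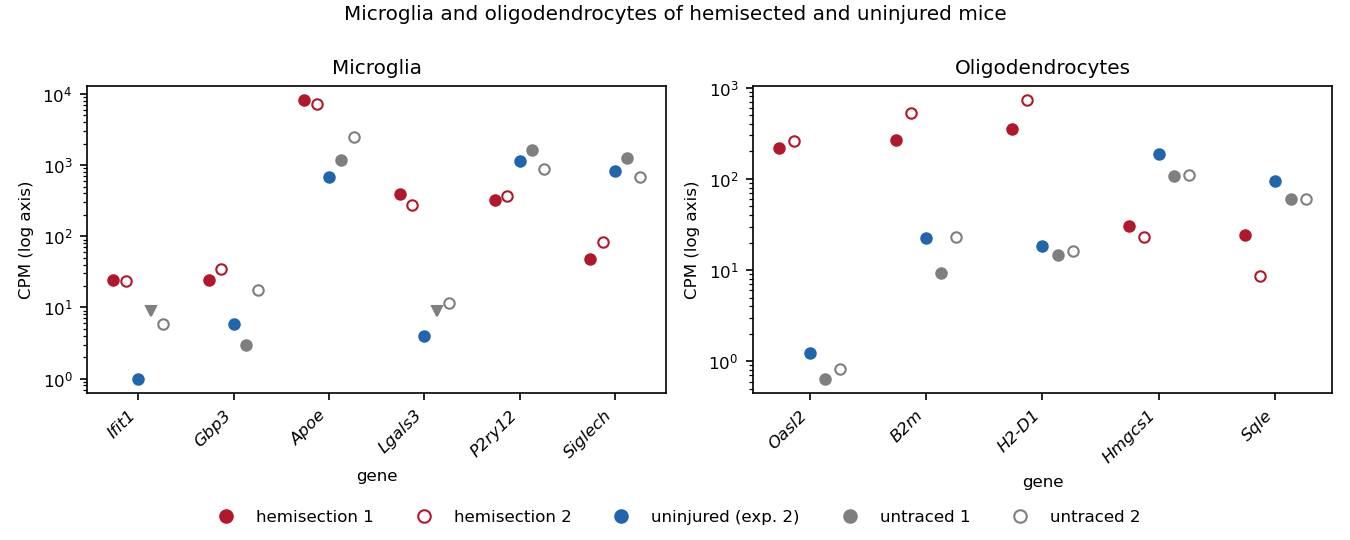
CPM (log axis) of genes in microglia and oligodendrocytes of hemisected and uninjured libraries, with replicate 1 filled and replicate 2 open. Downward triangles are libraries with 0 counts drawn at the floor of 3 counts.

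The comparison of regenerating with uninjured traced neurons asked what distinguishes neurons that regrew their axons. Ebf2, a transcription factor gene of dorsal excitatory neurons, Nmu, which encodes neuromedin U, and Spidr, which encodes a scaffold of DNA repair, were higher in the regenerating library. Pbx3, a homeobox gene of spinal neurons, Epb41, which encodes a link of membrane and actin skeleton, and Cenpv, which encodes a centromere protein, were lower. The regenerating library held 135012 UMIs in 238 neurons, so most values rest on few counts, and the experiment cannot be told apart from the regeneration. In the edgeR quasi-likelihood test 32 genes were called, 25 higher and 7 lower, where the median log2 fold change of all genes was −0.28. In nuclei with at least 1000 UMIs, which left 32 of the 238 regenerating nuclei, 14 genes were called, 6 of the 32 called genes among them. With equal numbers of the name families DE and VEP, 15 nuclei per library, 31 were called, 1 of the 32 among them. Ebf2 was at 926 CPM against 222 ± 29.8 CPM (SD, n = 2), a log2 fold change of 2.01 (adjusted p = 0.00971). Spidr and Mylip rose by 4.28 and 4.40, with 26 UMIs in 25 nuclei and 16 UMIs in 15 nuclei. Nmu rose by 4.31 with 11 UMIs in 5 nuclei, but turned to −7.19 in nuclei with at least 1000 UMIs, a fitted value from 0 counts. Single nuclei gave 18 of the 19 Kcnj12 UMIs, 15 of the 17 Cdk5rap1 UMIs, 22 of the 24 Fam167a UMIs and all 15 Lrrc36 UMIs. For Kcnj12 and Cdk5rap1 the log2 fold changes were 3.70 and 3.83. Fam167a had 24 counts against 2 (ratio 159, 95% counting interval 39.4 to 1385) and Lrrc36 15 against 3 (ratio 66.1, 18.7 to 356). Cenpu had 9 UMIs in 3 nuclei against 0, at least 39.7-fold more over the group. Epb41 and Pbx3 fell by 2.26 and 1.65 in log2 units. Cenpv had 0 counts against 233, at most 0.17 of its level over the group. Etfa and Zc3h15 had 0 counts, with log2 bounds of −1.87 and −1.85. Mpp7 had 1 count against 213 (16.1 times lower, 95% counting interval 2.86 to 639) and Fcho2 3 against 332 (8.37 times lower, 2.84 to 40.8). Cul2 missed the threshold (adjusted p = 0.0761), as did Hoxa7 (log2 fold change 1.16, adjusted p = 0.244) and Zfhx3 (−0.53, adjusted p = 0.418). Without traced replicate 1, 0 genes were called by edgeR (1548 at unadjusted p < 0.05), the named ones included, and without replicate 2 the calls of Etfa, Pbx3 and Zc3h15 were lost beside 28 genes called.

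Ebf2 was the 1 called of 7 glutamatergic identity genes in regenerating neurons (3 adjusted over the list alone, median 0.95, adjusted p = 0.266 with an estimated correlation). Nmu was the 1 called of 21 dorsal horn genes (1 adjusted over the list alone, median 0.30, adjusted p = 0.467 with an estimated correlation). Of 6 ependymal markers 0 were called (1 adjusted over the list alone, median 0.77, or 1.56 with genes at 0 counts at their bound, adjusted p = 0.467 with an estimated correlation). Cholesterol synthesis, mitochondrial and ribosomal protein genes had 0 called of 15, 13 and 30, with 4, 8 and 0 adjusted over the list alone. Their medians with genes at 0 counts at their bound were −0.43, −0.99 and −0.63, and their adjusted p with an estimated correlation was 0.266, 0.536 and 0.799. Of the regeneration-associated genes 0 were called, Gap43, which encodes a growth cone protein, among them (log2 fold change 0.89, adjusted p = 0.272). By share, 0 subtypes were called in the edgeR quasi-likelihood test, 5 at unadjusted p < 0.05. Among these were DE_Tac1 (0 of 238 nuclei, adjusted p = 0.0729), DE_Sox5_Qrfpr (7.14% against 0.625%, 17 nuclei against 1), MEP_Lmx1b_Satb1 and DE_Cck_Cpne4 (adjusted p = 0.237 each).

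The responses of regenerating neurons and of neurons after hemisection were set side by side. Their log2 fold changes correlated across 11601 genes with a Spearman coefficient of 0.145, and genes are not independent replicates. Called higher in both were 0 genes, where independent lists would share 0.237, and lower in both 0, where they would share 0.323, so that the lists were too short to show an overlap or its absence. In the test of the difference itself 13 genes were called, 10 of them higher in the regenerating response, Nmu and Spidr among them.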

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

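The tests of the uninjured library standing apart, of glial RNA and of free Chrm4 RNA were chosen only after the results they bear on were seen, and the tests of the subtype mixture and of the neighbours of Chrm4 before. The response of regenerating neurons, against uninjured traced neurons, was set against the response after hemisection, and the edgeR quasi-likelihood test of their difference called 13 genes. Spidr, Nmu, Kcnj12 and Cdk5rap1 were higher in the regenerating response by 4.85, 4.45, 4.32 and 3.79 in log2 units (adjusted p = 0.0272, 0.0253, 0.0351 and 0.0272). Fcho2 differed by −3.43 (adjusted p = 0.0272), and Cenpv by −3.02 with its 0 counts at the floor of 3 counts over the group (adjusted p = 0.0253). After hemisection alone these 6 genes had log2 fold changes of −0.57, −0.14, −0.62, 0.04, 0.31 and 0.47. In the regenerating library 1 nucleus gave 18 of the 19 Kcnj12 UMIs and 15 of the 17 Cdk5rap1 UMIs, while the 26 Spidr UMIs lay in 25 nuclei. The other 7 genes were Gm26992, Elfn2, Zfp710, Nfe2l1, Mbp, Tmed9 and Wsb1. Without traced replicate 1, 0 genes were called by edgeR (1522 at unadjusted p < 0.05), and without hemisection replicate 2, 23. DESeq2 called 23, all higher. DESeq2 and its size factors moved the median difference of all genes from −0.36 by 0.18 and 0.14, too little to turn the sign of any of the 6. The regenerating library is the only one of its experiment, so the regeneration cannot be told apart from the experiment.

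Lower transcripts after hemisection, 535 genes with mitochondrial, myelin and chaperone genes among them, were weighed first. Their median log2 fold change was −1.69 against the uninjured library of experiment 2 and −0.39 against the untraced neurons of experiment 1, which is consistent with that uninjured library standing apart as the source of most of the fall. Choosing genes by that library shrinks them against any other reference, but in 20 simulated data sets where these genes fell alike against both references the medians of the called ones were −1.80 and −1.76, and with falls of 0.5 times the observed size −1.37 and −1.20. The mixture of subtypes could be equalised only over 8 dorsal subtypes, with 77 nuclei per library. There the median over 447 genes was −1.62 beside −1.61 before. This argues against the mixture as the source of the fall in these subtypes. Other subtypes, motor neurons among them, did not enter this fit. For RNA of glia in that uninjured library, a test set beforehand was met, as 52.0% of these genes were higher in its non-neuronal nuclei, but so were 58.1% of all tested genes, and it was replaced after this was seen. In its place the share of glial RNA that each fall needs was compared with the share shown by glial markers. These were 5 abundant ones, Mbp, St18 and Mag among them. A median of 66.3% was needed and 4.49% shown, 14.8 times less, though 8.41% of the genes lay within 3 times. This argues against RNA with the profile of the non-neuronal nuclei for the set. Free RNA with another profile, such as RNA of all cells, was not tested. Microglia after hemisection also had 7 of 8 neuron markers and 10 of 10 oligodendrocyte markers called lower against that library. What set that library apart is not given in the sources used here. An injury response of genes not called against both references stays open. For genes called lower against both, injury was not told apart from the animal, as the hemisection libraries may come from the same animal.

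Interferon-response genes, 6 called higher in neurons after hemisection, were weighed next. Free RNA with the profile of microglial or oligodendrocyte nuclei is argued against. The called genes needed at least 5.22 times the glial share that markers show in the same neurons. For microglia 9.31% and 14.4% were needed beside 1.68% and 2.76% shown. A subtype mixture could be tested only over 8 dorsal subtypes, with 77 nuclei per library. It is argued against there by a median log2 fold change of 3.55 with equal numbers of each, beside 3.52 before, over 4 genes. The uninjured library standing apart is argued against by a median of 3.97 against the untraced neurons of experiment 1, beside 3.92. A response of neurons to interferon after the injury may therefore be put forward as a hypothesis, found and tested on the same libraries, of which the hemisection ones may come from 1 animal.

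Chrm4, at 805 counts after hemisection and 3 in the uninjured library, was weighed last, and its free-RNA test took 3 forms. The first, a bound on Chrm4 in non-neuronal nuclei of each library, decided replicate 2, where the upper bound was 1.76% of the level in neurons (1 UMI of 3162811), but not replicate 1, where it was 28.8%. The second, a difference between subtypes in each library, decided replicate 1 (permutation p = 1e-05, the smallest that 100000 permutations can give, over 807 nuclei) but not replicate 2 (permutation p = 0.163, 7 of 76 nuclei with a UMI), and the form used, the deciding test of each library, was chosen after all 4 values were seen. Free RNA is thus argued against by 1 test in each library. For reads of neighbouring genes, a fall of the tested genes within 50 kb was asked for, and the summed level of these 2, Ambra1 and Dgkz, rose by 64.6 CPM where Chrm4 rose by 93.0 CPM. Ambra1 lies upstream on the same strand, and reads running on from it would go with a rise, so that asking for a fall was wrong and this explanation stays open. A receptor sequence delivered by a vector or carried by a transgene could also be counted as Chrm4, which stays open and untested, since the use of one is not given in the sources used here.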

How the results depend on the processing

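The fits by name family, without the regenerating library, against experiment 1 and with another background for separability are tests chosen only after the results were seen. Of 525 values for 54 named genes and shares, 406 kept direction and side of the threshold, 106 lost the call, 2 gained one and 11 changed sign, with 2 further values without any count left out. The cause was not tested except where the number of samples, genes or counts gives it.

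Traced against untraced gave 42 genes, 234 without a filter on low counts (83 higher, 151 lower) and 13 in thinned libraries. With the animal number as a block 159 were called (65 higher, 94 lower, 42 shared). Equal numbers of the families DE and VEP, 15 nuclei per library, gave 0 of 3992 tested (164 at unadjusted p < 0.05 by edgeR). There Mecom, Zfhx3 and Cpq turned to −0.88, −0.14 and −0.77. Leaving out 1 library gave 19 (without traced replicate 1) to 93 genes (without untraced replicate 1). Shares gave 1 subtype, 2 with TMM factors, 2 with the block and 0 to 1 with a library left out. The block changed no other call, and 3 of the 11 called lists were too short for it.

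Hemisection gave 645 genes, 137 with DESeq2 (17 higher, 120 lower), 1101 without the filter, 2413 with only the libraries compared, 58 in thinned libraries and 22 against experiment 1. Leaving out a library gave 171 (without replicate 1) to 327 genes (without replicate 2), for which fewer samples are a cause. Hoxa7 was −0.29 against experiment 1, −0.00564 with DESeq2 and −0.14 to 0.21 with a library left out. With equal numbers of each of 8 dorsal subtypes, 77 nuclei per library, Hoxa7 was −0.56 and Zfhx3 −0.27. Shares had 0 called with either library left out and 0 against experiment 1, and TMM factors called another subtype in place of DE_Rreb1_Zim1. Genes within subtypes numbered 98, 11 to 47 with a library left out (without replicate 1 and replicate 2), 3 against experiment 1 and 480 by name family. Non-neuronal classes gave 2653, 442 (without replicate 2) to 2668, and 994 against experiment 1. The AUC of both hemisection replicates against the uninjured library exceeded that between them in 1 subtype and in 2 name families. With untraced replicate 1 of experiment 1 against that library as background, this held for 0 subtypes. In family DI the AUCs were 0.905 and 0.877 beside a background of 0.876, and in DE 0.794 and 0.841 beside 0.819.

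Regenerating neurons gave 32 genes, 185 without the filter, 88 with only the libraries compared, 14 in nuclei with at least 1000 UMIs and 0 (without traced replicate 1) to 28. DESeq2 gave 41 (39 higher, 2 lower), and equal numbers of the families DE and VEP, 15 nuclei per library, gave 31 with 1 shared. In deeper nuclei Cdk5rap1 and Nmu turned to −8.30 and −7.19 and with equal families Hoxa7 to −6.22, fitted values from 0 counts. The difference of the responses gave 13 genes, 23 with DESeq2, 199 without the filter, and 0 (without traced replicate 1) to 23 (without hemisection replicate 2). The 29 list calls became 0 with an estimated correlation and 0 with fry. The shared response kept its Spearman coefficient between 0.129 and 0.145.

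Not run, for want of nuclei or of a deposited broader level, were equal subtypes for the traced and regenerating contrasts and the shared response, traced genes within subtypes, a broader annotation, and minima of 50 nuclei for genes and 40 for separability. Depth was lowest in the regenerating library, with a median of 488 UMIs per neuron, and 4-fold changes of its contrast were recovered in 25.0% of simulated genes.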

Other observations

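The test of the subtype mixture behind the traced genes was chosen before its result was seen, so that no test in this part was chosen only after it. The hypothesis was that traced and untraced neurons differ because they hold different subtypes. Fold changes were computed from the subtype shares of experiment 1 and the subtype profiles of the uninjured library of experiment 2, which is not among the libraries compared. They gave the observed sign for 92.9% of the 42 called genes (39 genes). Their median size was 0.91 in log2 units beside 1.60 observed, or 56.9% of it, and across 7034 genes expected and observed values correlated with a Spearman coefficient of 0.444. This is consistent with the mixture of subtypes as a source of part of the traced genes. Arhgap6, Gad1 and Npy had −1.29, −1.14 and −2.42 expected beside −1.90, −1.62 and −2.37 observed. The mixture gave little of Nmu (−0.48 beside −3.26), Dqx1 (0.39 beside 6.82), Cul4b (0.13 beside 2.08), Ptgds (−0.27 beside −3.71) and Mal (−0.36 beside −4.05), and the opposite sign for the other 3 genes, mt-Atp6, mt-Co3 and mt-Nd3. A difference within subtypes stays open, since no subtype had enough traced nuclei for a test. For Mal and Ptgds, RNA of glia in the untraced libraries was not tested and stays open as well. The 390 Ptgds UMIs of untraced neurons lay in 240 of 477 nuclei, with at most 7 in 1 nucleus.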
